A study of Mus musculus with 7 samples.

How the data were processed

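Gene expression was measured in mouse CD4+ T cells from lymph nodes of C57BL/6-background (B6) females. Per the labels' protocols the cells were sorted as CD4+ after exclusion of cells carrying CD19, CD8a, CD11b, CD11c, CD25 or NK1.1, so B cells, cytotoxic T cells, myeloid cells, NK cells and existing regulatory T (Treg) cells were gated out. They were transduced with retroviral vectors encoding FOXP3, the lineage factor of Treg cells, alone or together with GATA1, a transcription factor of the erythroid and megakaryocytic lineages, and then sorted into fractions by Thy1.1, the surface reporter that tracks the FOXP3 vector. The series holds 7 arrays, with 1 array for each condition: low, intermediate and high FOXP3 bins of cells labelled FOXP3, the same 3 bins of cells labelled FOXP3+GATA1, and cells with the empty vector. The empty vector is labelled pMIG, and its array has no FOXP3 bin. RNA was extracted with TRIzol and labelled with biotin for Affymetrix whole-transcript arrays, per the labels' protocols.

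The deposited values are intensity values per probe set on a linear scale. Affymetrix Power Tools and RMA are named for them, without versions, per the submitters' processing notes. RMA corrects the background, makes the arrays' distributions alike and combines the probes of a set by median polish. Whether the 7 arrays were processed in 1 run, and whether probe sets were filtered, is not given in the sources used here. The table held 24922 probe sets for the 7 arrays, and every column of values belonged to 1 of the 7 samples. In 65.1% of the genes tested, at least 2 of the 7 arrays carried exactly the same value, which median polish can produce, and 48 genes had a single value on all 6 FOXP3-transduced arrays. Such ties lower a gene's apparent spread.

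The log2 of each deposited value was taken, and the authors' normalization was kept. Probe sets were named through the platform annotation supplied with the table: 21425 had 1 gene symbol, 1399 had several and 2098 had none. The Entrez identifiers of 21347 single-symbol probe sets were found in the RefSeq gene table, and 0 symbols needed updating. Only probe sets with 1 symbol were used, and for a gene with several the probe set with the highest mean was kept, which gave 19752 genes. Genes whose mean over the 7 arrays lay at or above the 30th percentile (log2 intensity 4.90) were tested, 13826 in all.

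The 6 FOXP3-transduced arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values). The model had a term for the arm and a 3-level term for the FOXP3 bin, because the bins of the arms were matched, and it left 2 residual degrees of freedom. With 1 array per condition, the spread of this fit holds any dependence of the arm difference on the bin as well as noise. No source says that the bins came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Reported from this fit were the difference between arms (labelled FOXP3+GATA1 minus labelled FOXP3, the mean over 3 bins) and the FOXP3 level effect (high minus low bin, the mean over 2 arms). Whether the difference between arms changed with FOXP3 level was tested in a second fit as the product of the arm and a bin score of -1, 0 and 1. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05 was called. Errors given with ± are limma standard errors unless named as SD.

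The single empty-vector array gives no spread of its own, so a limma test against it could only borrow the spread of the 6 transduced arrays and was run as an alternative. Each arm was set against it by a fixed rule of size, at least 2-fold in the same direction in all 3 bins, and gene lists were set beside 10000 random lists of the same size matched on mean expression in 20 classes, as a description of these arrays. The 2 arms share that vector array, so similarities between the 2 comparisons were not tested.

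In all, 38 gene lists were written from general knowledge. They covered the Treg signature, T helper and activation programmes, erythroid and other GATA1-related genes, proliferation, metabolism, stress and the other cell types the gate could hold. The 37 lists with at least 5 genes tested were compared with all other genes by limma's camera with its preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The fry test asked whether a list's genes moved one way, without comparing them with other genes. For each list the number of genes past the test is given over all genes tested and adjusted over the list alone.

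The named genes followed a fixed rule. Foxp3, Gata1 and Thy1 came first. For the arms, the 12 highest and 12 lowest differences among called genes with the same direction in all 3 bins were named. Where fewer than 5 genes passed in a direction, and for the interaction, the 5 of lowest p per direction were named. For the FOXP3 level effect, only genes with the same direction in both arms could be named. Against the vector, the 8 largest mean differences per direction were named. Members of the fixed lists were named if called, or if among the 4 with the largest difference. Gene models without a name, olfactory receptors and antigen receptor segments were counted but not named. The design, the lists, this rule and most of the alternatives below were fixed before the data were examined.

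The fits were tested on simulated values for the 13826 genes with the prior spread of the real fit. The simulated noise was independent between genes and held no ties, so the shares below may not hold for the real values. For the difference between arms, 45% of 100 genes changed by 0.5 log2 and 87% of 100 genes changed by 1 log2 were recovered, with 6 unchanged genes among 138 calls. For the FOXP3 level effect the shares were 8% and 78%, with 1 unchanged gene among 87 calls. For the interaction they were 15% and 89% per bin step, with 8 unchanged genes among 112 calls. A list of 60 genes shifted by 0.3 log2 between arms was recovered by camera with the preset correlation, where 1 other list passed too, and the shifted list had an adjusted p of 0.0827 with an estimated correlation.

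The alternatives tried were no filter and a 50th-percentile filter, centring of each array on its median, quantile normalization, the mean of a gene's probe sets, an intensity trend or robust fitting in eBayes, other forms of the bin term, an added 1.5-fold minimum, other rules against the vector, and leaving out each bin or array. Arrays have no read depth, and their number limits the precision. Probe sets with no symbol or several symbols entered no comparison. Tables were built in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.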

Results

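Transcript levels were profiled on 7 arrays of CD4+ T cells to ask how FOXP3, at different levels and with or without GATA1, affects the Treg transcriptional signature, with GATA1 standing for a set of factors thought to act with FOXP3. There was 1 array for each of the 3 FOXP3 bins in each arm and 1 for the empty vector, so no condition had a replicate. The median intensity of the arrays lay between 56.8 and 62.3. The interquartile range of the log2 values was 2.92 to 3.02 on the arrays labelled FOXP3, 3.08 to 3.16 on those labelled FOXP3+GATA1 and 3.17 on the vector array, so the arrays labelled FOXP3 had the narrower signal range.

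The transduced genes were examined first. Foxp3 signal was above the vector array (log2 intensity 6.78) on all 6 transduced arrays, by 0.52 ± 0.06 (SD over 3 bins) on those labelled FOXP3 and by 0.82 ± 0.21 on those labelled FOXP3+GATA1. It did not follow the bins on the arrays labelled FOXP3, at 7.36, 7.29 and 7.24 from low to high, while on those labelled FOXP3+GATA1 it was 7.49, 7.47 and 7.85. The difference in Foxp3 between the arms was 0.13, 0.18 and 0.60 from low to high, with a mean of 0.31 ± 0.11 that did not pass limma's test (adjusted p = 0.180) but passed after each array was centred on its median (adjusted p = 0.0329), so equal Foxp3 transcript in matched bins was not shown. The Gata1 probe set went against the labels. It read 6.87, 6.80 and 7.27 from low to high on the arrays labelled FOXP3, 6.76, 6.77 and 6.36 on those labelled FOXP3+GATA1 and 6.91 on the vector array. The difference between arms was -0.35 ± 0.19 and did not pass limma's test (adjusted p = 0.302). Whether these probe sets lie in the transduced sequences is not given in the sources used here, so the Gata1 signal neither bears out nor excludes the labels, and every direction below rests on them. Thy1, whose endogenous form these cells also express, lay between 11.63 and 11.96 on the 7 arrays. From low to high it read 11.63, 11.80 and 11.96 on the arrays labelled FOXP3 and 11.82, 11.81 and 11.93 on those labelled FOXP3+GATA1, against 11.81 on the vector array. Its high minus low difference was 0.22 ± 0.08 and did not pass limma's test (adjusted p = 0.482).

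**Figure D1:**
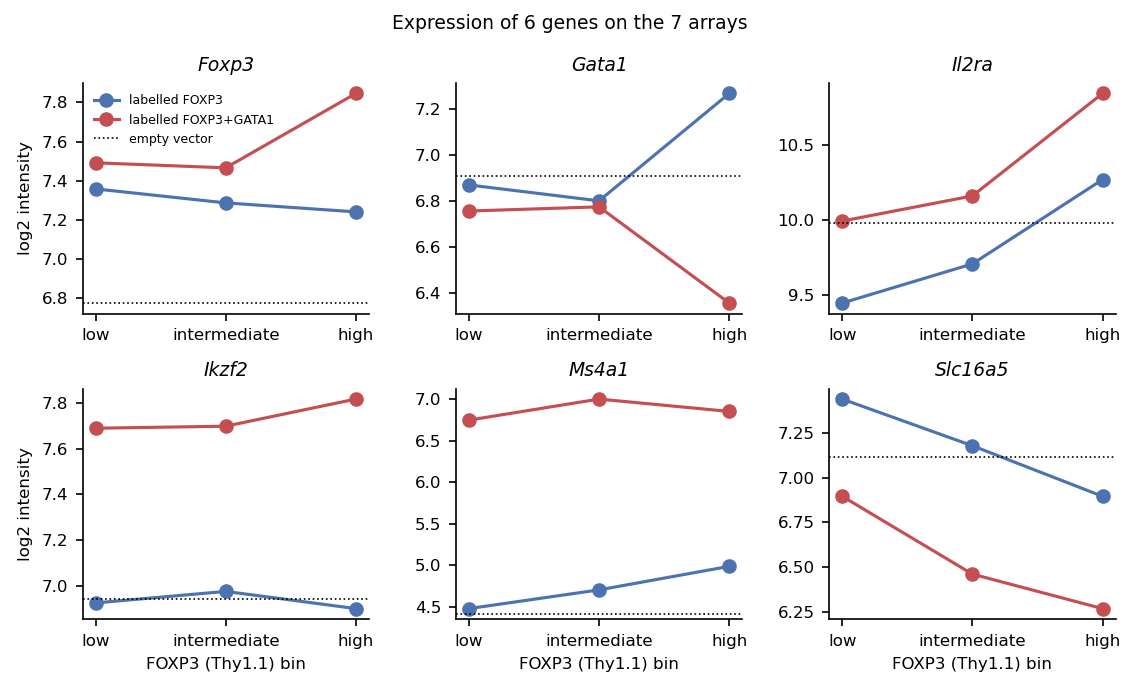
Log2 intensity of 6 genes (y axes, each with its own range) in the low, intermediate and high FOXP3 bins (x axis) for the arrays labelled FOXP3 (blue) and FOXP3+GATA1 (red), with the empty-vector array as a dotted line. Each point is 1 array. Il2ra was highest in the high bin of both arms, Ikzf2 and Ms4a1 separated the arms in every bin, and the Gata1 probe set did not follow the labels.

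The comparison of the arms asked what GATA1 adds in matched FOXP3 bins. On the arrays labelled FOXP3+GATA1, a part of the genes of the Treg signature, T cell activation, cell division and B cells was called higher than on those labelled FOXP3. Among Treg genes, Gzmb, which encodes the cytotoxic protease granzyme B, was higher by 1.59 ± 0.13 log2 (3.02-fold). Tnfrsf9, the costimulatory receptor 4-1BB, was higher by 1.23 ± 0.08, Ikzf2, the Treg transcription factor Helios, by 0.80 ± 0.06, and Il2ra, the interleukin-2 receptor alpha chain CD25, by 0.53 ± 0.05. Among the called genes, the largest differences were in genes known from B cells and other antigen-presenting cells: Ms4a1, which encodes CD20, by 2.14 ± 0.10 and the invariant chain Cd74 by 2.13 ± 0.27. In all, limma called 230 genes higher and 16 lower at an adjusted p under 0.05, each in the same direction in all 3 bins, and 13 of them differed at least 2-fold.

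Of the 60 measured genes that are typically higher in Treg cells, 54 were higher on the arrays labelled FOXP3+GATA1, with a median of 0.29. The test called 13 of them higher and 0 lower (32 and 0 adjusted over the list alone). Besides the 4 above these were Cd83 (0.97 ± 0.08), the phosphatase Dusp4 (0.80 ± 0.08), the transcription factor Irf4 (0.75 ± 0.09), the neuropilin Nrp1 (0.72 ± 0.09), Swap70 (0.68 ± 0.09), Socs2 (0.59 ± 0.06), Samsn1 (0.57 ± 0.05), the inhibitory receptor Tigit (0.55 ± 0.06) and Tnfrsf4, the receptor OX40 (0.54 ± 0.07). Penk, the precursor of enkephalin, was at 1.57 ± 0.24 without passing (adjusted p = 0.0591). The list stood above all other genes by camera with the preset correlation (adjusted p = 4.4e-14). It did not pass with the correlation estimated from the arrays (adjusted p = 0.338 with an estimated correlation). The simulated list of 60 genes shifted by 0.3 log2 did not pass in that form either (camera adjusted p = 0.0827). That was 1 simulated draw with noise independent between genes, and unshifted lists were not compared in that form. How often that form misses a shifted list is therefore not known, and the failure of the real list is not set aside. The list's median difference was 0.32 in the low, 0.30 in the intermediate and 0.25 in the high bin, and 18 of its genes also stand in other lists.

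Of 26 measured genes that are typically lower in Treg cells, 1 was called lower and 0 higher (6 and 2 adjusted over the list alone). The called gene was the monocarboxylate transporter Slc16a5, at -0.63 ± 0.06. The list's largest difference was that of Nrn1, at 0.88 ± 0.12 and so opposite to the Treg direction, and it did not pass, nor did Il6ra (-0.45 ± 0.07) and Igfbp4 (-0.43 ± 0.10). The list's median was -0.07, with a camera adjusted p of 0.161 (adjusted p = 0.568 with an estimated correlation), and after quantile normalization the camera adjusted p was 0.0132. Among 23 transcription factors associated with Treg cells, 4 were called higher (8 adjusted over the list alone): Nr4a1 (0.82 ± 0.09), Nr4a3 (0.75 ± 0.08), Ikzf2 and Irf4. That list's median was 0.03 and turned to -0.05 after quantile normalization, while camera placed it higher (adjusted p = 0.0137, and adjusted p = 0.403 with an estimated correlation), a call that was also lost after quantile normalization (adjusted p = 0.133).

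Genes induced by T cell activation had a median difference of 0.54. Of 17 measured, 8 were called higher (14 adjusted over the list alone), among them the transferrin receptor Tfrc (0.78 ± 0.09) and Myc (0.54 ± 0.05), and 9 of the 17 also stand in other lists. Camera gave an adjusted p of 6.51e-09 (adjusted p = 0.338 with an estimated correlation). Of 9 inhibitory receptor genes, Tigit was called, with Pdcd1, which encodes PD-1, at 0.51 ± 0.09 without passing. Of 11 follicular helper genes, Cd200 was called (0.54 ± 0.05). Of 15 Th1 genes, Gzmb and the chemokine receptor Cxcr6 (0.71 ± 0.09) were called. The camera adjusted p of these 3 lists was 0.00211, 0.02 and 0.00265 (adjusted p = 0.338 with an estimated correlation for each). Adjusted over the list alone, 4 inhibitory receptor genes and 5 follicular helper genes were higher, and 7 Th1 genes were higher and 2 lower.

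Among 18 chemokine and chemokine receptor genes, 5 were called higher: Ccl22 (0.78 ± 0.05), Ccl1 (0.71 ± 0.06), Cxcr6, Ccr2 (0.57 ± 0.07) and Ccr4 (0.50 ± 0.07). Adjusted over the list alone, 8 were higher and 1 lower. Ccl3, a ligand for CCR1 and CCR5, was at 1.80 ± 0.25 without passing (limma adjusted p = 0.0535). The list's camera adjusted p was 0.000101 (adjusted p = 0.338 with an estimated correlation), and 13 of its 18 genes also stand in other lists. Genes of effector cytokines had 0 of 14 called (2 higher adjusted over the list alone; camera adjusted p = 0.065, adjusted p = 0.341 with an estimated correlation, and 0.0132 with the preset correlation after quantile normalization, where the list passed as higher), with Il13 at 0.55 ± 0.09. Of 11 Th2 genes, Ccr4 was called (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.193). Of 7 Th17 genes 0 were called (2 higher adjusted over the list alone; camera adjusted p = 0.727).

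B cell genes moved with the arm. All 14 measured B cell markers were higher on the arrays labelled FOXP3+GATA1, with a median of 0.93, and 9 were called (12 adjusted over the list alone). They included the major histocompatibility complex class II genes H2-Aa (1.97 ± 0.16), H2-Ab1 (1.46 ± 0.18) and H2-Eb1 (1.19 ± 0.14), the B cell receptor subunit Cd79b (0.63 ± 0.05), the B cell transcription factor Pax5 (0.50 ± 0.05) and Cd22 (0.71 ± 0.08). The camera adjusted p was 1.21e-10 (adjusted p = 0.338 with an estimated correlation). On the vector array, 5 of the 14 lay above the array's median. Of 7 plasma cell genes, Irf4 was called, which activated T cells also express (4 adjusted over the list alone; camera adjusted p = 0.0344, and adjusted p = 0.338 with an estimated correlation). The genes Ly86 (1.22 ± 0.07), Marcks (1.19 ± 0.05), the NADPH oxidase subunit Cybb (1.15 ± 0.12) and the costimulatory ligand Cd80 (1.03 ± 0.12), also known from antigen-presenting cells, were among the 12 largest differences of the genes called higher.

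Genes of proliferation were higher as groups. All 23 measured cell cycle and mitosis genes were higher on the arrays labelled FOXP3+GATA1, with a median of 0.55, and 11 were called (22 adjusted over the list alone), among them the checkpoint kinase Bub1 (0.89 ± 0.10), Mki67, which encodes the Ki-67 antigen (0.80 ± 0.08), Kif11 (0.75 ± 0.07) and Ttk (0.72 ± 0.06). All 24 DNA replication genes were higher, with a median of 0.51, and 8 were called (21 adjusted over the list alone), among them Mcm6 (0.78 ± 0.05), Ccne2 (0.72 ± 0.08) and the polymerase gene Pola1 (0.68 ± 0.05). The camera adjusted p was 1.64e-15 and 2.16e-14 (adjusted p = 0.338 with an estimated correlation for both).

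Metabolic and biosynthetic genes followed. Of 20 genes in the glycolysis list 4 were called higher (14 adjusted over the list alone): Bnip3 (0.78 ± 0.08), Tpi1 (0.71 ± 0.09), Pgk1 (0.58 ± 0.05) and Hk2 (0.46 ± 0.05). Bnip3 stands in that list but does not encode a glycolytic enzyme. Of 20 genes of the unfolded protein response 5 were called higher (14 adjusted over the list alone), led by the asparagine synthetase Asns (1.07 ± 0.10) and the chaperone Hsp90b1 (0.56 ± 0.07). Of 19 cholesterol synthesis genes Sqle (0.63 ± 0.05) and Msmo1 (0.46 ± 0.06) were called (7 adjusted over the list alone), and of 24 ribosome biogenesis genes Nop58 (0.62 ± 0.05) was called (14 adjusted over the list alone). The camera adjusted p of these 4 lists was 1.76e-06, 3e-06, 0.00196 and 3.15e-06 (adjusted p = 0.338 with an estimated correlation for each). Of 28 oxidative phosphorylation genes cytochrome c, Cycs, was called (0.44 ± 0.05; 1 adjusted over the list alone). That list's camera adjusted p was 0.0432 (adjusted p = 0.338 with an estimated correlation), and after quantile normalization its median turned from 0.07 to -0.02 and the call was lost (adjusted p = 0.948).

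Naive and central memory genes had a median of -0.18, and 13 of 14 were lower on the arrays labelled FOXP3+GATA1, with 0 called (6 lower and 1 higher adjusted over the list alone). Klf2, a transcription factor of quiescent T cells, was at -0.40 ± 0.09 and the egress receptor S1pr1 at -0.24 ± 0.07. Camera placed the list lower (adjusted p = 0.00329, and adjusted p = 0.538 with an estimated correlation). Of 21 type I interferon response genes 19 were lower, with 0 called in either form and a median of -0.07. Ifit3 was at -0.48 ± 0.16 and Oas1a at -0.40 ± 0.12 (camera adjusted p = 0.0102, and adjusted p = 0.429 with an estimated correlation).

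Among the genes that could be tested, those of the lineages that GATA1 directs were not called in either direction. Of 36 erythroid genes written 16 were tested, and the globin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 were not matched to a gene in the table. On the vector array, 5 of 16 erythroid, 10 of 16 megakaryocyte and 3 of 11 mast cell, basophil and eosinophil genes lay above the array's median. Most erythroid and mast cell genes tested thus had low signal, which limits these results. Of 16 erythroid genes 0 were called (1 higher and 2 lower adjusted over the list alone), with Icam4 at -0.34 ± 0.06, Ermap at -0.31 ± 0.06 and Alas2, the erythroid enzyme of haem synthesis, at 0.03 ± 0.05. The camera adjusted p was 0.096. Of 16 megakaryocyte genes, 12 haem synthesis genes and 21 GATA1 partner genes, 0 were called in either form, with camera adjusted p of 0.299, 0.758 and 0.538. The fry test, which does not compare with other genes, passed the GATA1 partner list as higher (adjusted p = 0.0455), with a median of 0.03. Of 11 mast cell, basophil and eosinophil genes 0 were called in either form, with Cebpa at -0.27 ± 0.11. Camera placed that list lower (adjusted p = 0.0497, and adjusted p = 0.338 with an estimated correlation), and its adjusted p was 0.61 after quantile normalization.

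The remaining lists gave few calls. T cell receptor signalling (19 genes, camera adjusted p = 0.576), ribosomal proteins (23, 0.877), interferon gamma response and class I genes (16, 0.65), p53 targets (15, 0.278), myeloid (11, 0.395), stromal (8, 0.0667), CD8 T cell (9, 0.364) and gamma delta T cell markers (5, 0.65) had 0 genes called. Adjusted over the list alone, Sparc among the stromal markers was lower and Nkg7 among the CD8 T cell markers higher. The 4 NK cell markers measured, too few for a list test, had a median of 0.16. Of 18 heat shock and immediate early genes Hsp90aa1 was called (0.66 ± 0.05; 3 adjusted over the list alone; camera adjusted p = 0.12). Of 12 housekeeping genes Pgk1 was called (2 adjusted over the list alone; camera adjusted p = 0.0224, adjusted p = 0.429 with an estimated correlation and 0.127 after quantile normalization).

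Of the 16 genes called lower, the 12 named ones were Slc16a5, Lhfp (-0.60 ± 0.08), the oligodendrocyte factor Olig1 (-0.57 ± 0.07), Zfp747 (-0.56 ± 0.07), Hid1 (-0.52 ± 0.07), Krtap19-4 (-0.51 ± 0.06), H2-M10.3 (-0.50 ± 0.05), the surfactant gene Sftpa1 (-0.46 ± 0.06), Col8a2 (-0.45 ± 0.05), Wnt8a (-0.40 ± 0.05), Hrh3 (-0.39 ± 0.05) and Paqr7 (-0.37 ± 0.05). Several are tissue-restricted genes measured at low intensity here. The share of called genes that were higher was 93.5%, and it was 66.9% after quantile normalization, with 555 higher and 275 lower.

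By camera with the preset correlation 17 lists were higher and 3 lower, by fry 17 passed, and with an estimated correlation 0 passed. The 2 sets of 17 were not the same: 15 of the lists higher by camera passed fry. The 3 lower lists did not pass it: naive and central memory (fry adjusted p = 0.147), type I interferon (0.147) and mast cell, basophil and eosinophil genes (0.097). The form with an estimated correlation also missed the shifted list in the 1 simulated draw, whose noise was independent between genes. How often it misses a shifted list is not known, so which lists moved is not settled. The gene calls lay close to the threshold. The lowest adjusted p from limma was 0.0392, and 2088 genes were higher and 1429 lower at an unadjusted p under 0.05, against 691.3 expected for both together. The count fell to 0 without the expression filter and to 0 when the low, the intermediate or the high bins were left out, which leaves 1 residual degree of freedom, and 13 higher and 0 lower genes were called without the bin term.

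**Figure D2:**
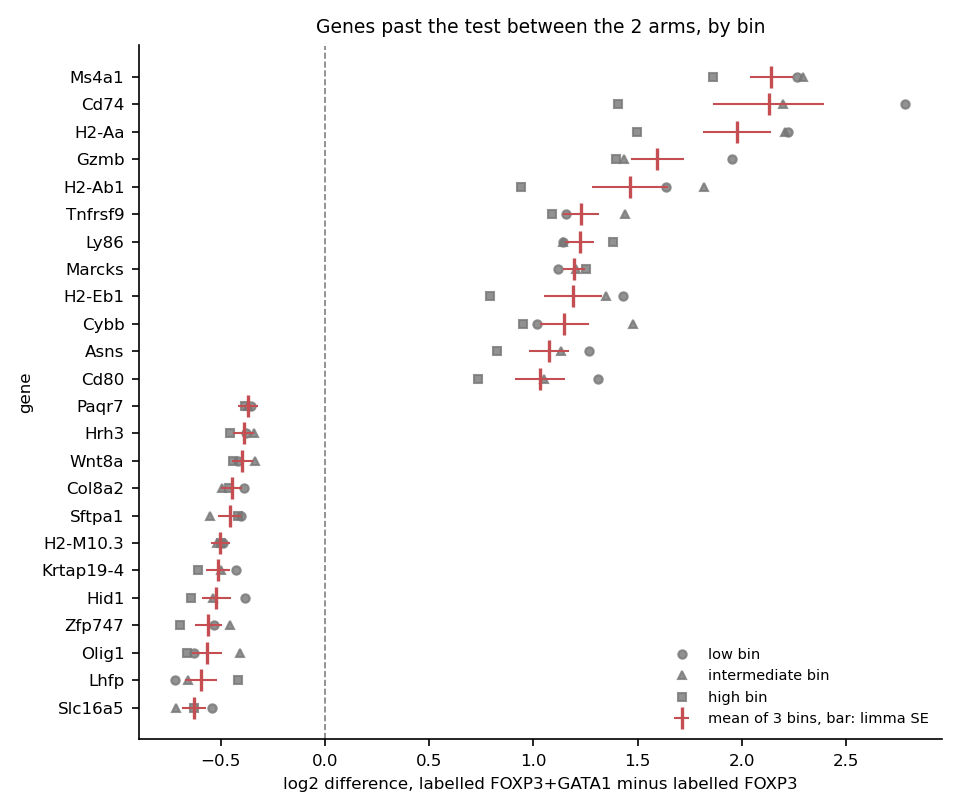
Log2 difference between the arms (x axis, labelled FOXP3+GATA1 minus labelled FOXP3) for the 12 highest and 12 lowest called genes (y axis). Grey symbols are the differences in the low, intermediate and high bins, and red marks are the mean of 3 bins with the limma standard error. Every gene lay on the same side of 0 in all 3 bins, as the naming rule required. The means ran from 2.14 for Ms4a1 to -0.63 for Slc16a5.

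The comparison of bins asked what changes with the level of FOXP3. The genes of lowest p that were higher in the high than in the low bins were Il2ra, by 0.84 ± 0.06 log2, Socs2, a feedback inhibitor of cytokine signalling, by 0.88 ± 0.07, the steroid-synthesis enzyme Cyp11a1 by 0.95 ± 0.08, the chemokine receptor Ccr2 by 0.99 ± 0.08 and the fatty acid synthesis enzyme Acaca by 0.67 ± 0.06. Those lower were Slc16a5, at -0.58 ± 0.07, the transcription factor Myb at -0.49 ± 0.07, Olig1 at -0.61 ± 0.09, Ppfia4 at -0.52 ± 0.08 and the microRNA gene Mir504 at -0.42 ± 0.06. All were picked among genes that differed in the same direction in both arms, so that agreement was set by the rule. None of these named genes passed limma's test over all genes, with a lowest adjusted p of 0.353. After each array was centred on its median, Il2ra and Socs2 (limma adjusted p = 0.00821), Cyp11a1 and Ccr2 (0.00604) and Acaca (0.0222) passed. The test called 0 genes higher and 0 lower, with 886 higher and 505 lower at an unadjusted p under 0.05.

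Lists gave more. All 24 DNA replication genes were higher in the high bins, with a median of 0.40, and 19 were higher adjusted over the list alone, among them Pola1 (0.59 ± 0.06) and Mcm6 (0.52 ± 0.06). Of 60 genes typical of Treg cells 44 were higher, with a median of 0.11, and 5 were higher adjusted over the list alone: Gzmb (1.06 ± 0.16), Socs2, Il2ra, Dusp4 (0.56 ± 0.10) and the interleukin-2 receptor beta chain Il2rb (0.53 ± 0.10). The camera adjusted p was 2.59e-17 and 2.52e-06 (adjusted p = 0.497 with an estimated correlation for both). Of 26 genes typically lower in Treg cells 21 were lower, with a median of -0.13, and Slc16a5 was lower adjusted over the list alone (camera adjusted p = 7.35e-05, and adjusted p = 0.497 with an estimated correlation).

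Glycolysis (median 0.23, 10 of 20 genes higher adjusted over the list alone), the unfolded protein response (0.24, 7 of 20) and cholesterol synthesis (0.14, 1 of 19) were higher with camera adjusted p of 2.34e-09, 2.87e-06 and 7.35e-05, as were ribosome biogenesis (0.12, 2 of 24; 0.000227) and oxidative phosphorylation (0.09, 1 of 28; 0.000255), with an adjusted p = 0.497 with an estimated correlation for each. Examples from these lists were Bnip3 (0.79 ± 0.10), Tpi1 (0.52 ± 0.11), Asns (0.65 ± 0.12) and Cycs (0.47 ± 0.06). Cell cycle genes were higher (0.25, 4 of 23; camera adjusted p = 5.97e-09, and adjusted p = 0.608 with an estimated correlation). Naive and central memory genes were lower (-0.15, 0 of 14; camera adjusted p = 0.000255, and adjusted p = 0.608 with an estimated correlation), as was T cell receptor signalling (-0.11, 0 of 19; camera adjusted p = 0.00507, and adjusted p = 0.617 with an estimated correlation).

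T cell activation (0.21, 4 of 17; camera adjusted p = 0.0496, and adjusted p = 0.617 with an estimated correlation), interferon gamma response and class I (0.03, 2 of 16; camera adjusted p = 0.0369, and adjusted p = 0.768 with an estimated correlation), housekeeping (0.05, 1 of 12; camera adjusted p = 0.0369, and adjusted p = 0.608 with an estimated correlation) and Th17 genes (-0.13, 0 of 7, lower; camera adjusted p = 0.0372, and adjusted p = 0.497 with an estimated correlation) passed camera narrowly. After quantile normalization none of these 4 passed, and oxidative phosphorylation did not either (adjusted p = 0.0731). The 14 B cell markers had a median of 0.07 between bins (camera adjusted p = 0.818). By camera 11 lists were higher and 4 lower, by fry 0 lists passed, and with an estimated correlation 0 passed.

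**Figure D3:**
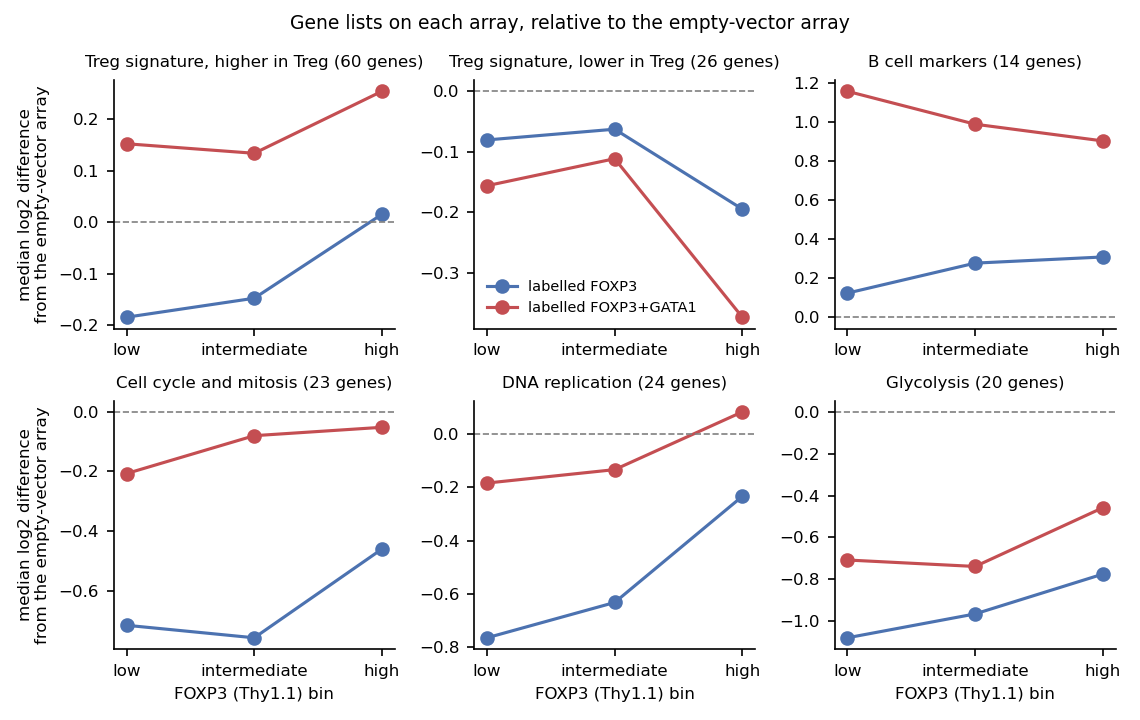
Median log2 difference from the empty-vector array (y axes, each with its own range) over the genes of 6 lists in the low, intermediate and high FOXP3 bins (x axis), for the arrays labelled FOXP3 (blue) and FOXP3+GATA1 (red). Each point is 1 array against the same single vector array, marked by the dashed line at 0. The medians of Treg genes, cell cycle, DNA replication, glycolysis and B cell markers lay above those of the other arm on the arrays labelled FOXP3+GATA1 in each bin.

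The interaction asked whether the difference between arms changed with FOXP3 level, and limma called 0 genes, with a lowest adjusted p of 0.917 and 304 positive and 316 negative slopes at an unadjusted p under 0.05. The genes of lowest p with a difference that grew from low to high bins were Vaultrc5 (0.51 ± 0.05 per bin), the kynurenine pathway enzyme Kynu (0.45 ± 0.06), Tmem38b (0.37 ± 0.06), the small nucleolar RNA gene Rnu3a (0.45 ± 0.07) and the cytokine Il4 (0.36 ± 0.06). Those with a slope of the opposite sign were Cd74 (-0.69 ± 0.06), the B cell factor Spib (-0.53 ± 0.05), Acot10 (-0.48 ± 0.06), Gzma, which encodes granzyme A (-0.39 ± 0.05), and the cohesion gene Esco2 (-0.37 ± 0.05). None of the 10 passed.

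Set against the single empty-vector array, which gives no replicate check, the arrays labelled FOXP3 stood out by lower genes of glycolysis and the response to low oxygen. Values are the mean over 3 bins with the SD. The 8 largest differences were Egln3, an oxygen-sensing prolyl hydroxylase (-2.33 ± 0.22), the aldolase Aldoc (-1.82 ± 0.34), Bnip3 (-1.81 ± 0.43), the transcription factor Bhlhe40 (-1.67 ± 0.41), the lactate exporter Slc16a3 (-1.56 ± 0.23), Ankrd37 (-1.49 on each array), Ero1a (-1.41 ± 0.28) and the glucose transporter Slc2a1 (-1.38 ± 0.26). In all, 12 genes were at least 2-fold lower and 0 at least 2-fold higher in all 3 bins, and the 12 became 30 without the high bins, where the rule asks for fewer bins.

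As a group, the 20 glycolysis genes lay below the vector on all 3 arrays labelled FOXP3, with a median of -0.94. The cell cycle list (-0.64) and DNA replication list (-0.52) lay below it too, and 0 of 10000 matched random lists were as low as any of the 3. The genes typical of Treg cells had a median of -0.12, as low as 25 of 10000 random lists, with 9 genes higher and 19 lower than the vector in all 3 bins, and the median was -0.18 in the low, -0.15 in the intermediate and 0.02 in the high bin. Unfolded protein response genes stood at -0.21 (as low as 9 of 10000), heat shock and immediate early genes at -0.16 (25 of 10000) and T cell activation genes at -0.17 (187 of 10000). Th1 genes (0.22) and chemokine genes (0.23) lay above the vector, as high as 0 of 10000 random lists, and B cell markers stood at 0.21, as high as 16 of 10000. GATA1 partner genes stood at 0.07, as high as 138 of 10000.

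On the arrays labelled FOXP3+GATA1, the largest differences above the vector lay in class II and B cell genes, the chemokine gene Ccl3 and the Treg genes Penk and Gzmb. The 8 largest differences were H2-Aa (2.91 ± 0.18), Ccl3 (2.65 ± 0.36), Penk (2.49 ± 0.32), Ms4a1 (2.45 ± 0.13), Cd74 (2.17 ± 0.09), the low-affinity IgE receptor Fcer2a (2.11 ± 0.44), Gzmb (1.95 ± 0.41) and Ly86 (1.73 ± 0.12). The genes at least 2-fold lower were Aldoc (-1.85 ± 0.13), Egln3 (-1.76 ± 0.23), Ankrd37 (-1.61 ± 0.12), Slc16a3 (-1.28 ± 0.19) and the collagen prolyl hydroxylases P4ha2 (-1.09 ± 0.08) and P4ha1 (-1.07 ± 0.06). In all, 12 genes were higher and 6 lower, and the 6 became 12 without the high bins, where the rule asks for fewer bins.

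The genes typical of Treg cells had a median of 0.17 against the vector on these arrays, as high as 0 of 10000 matched random lists, and those typically lower in Treg cells had a median of -0.20, as low as 0 of 10000. Genes of T cell activation (0.35), Th1 cells (0.42), chemokines (0.44), plasma cells (0.41), ribosome biogenesis (0.20), the unfolded protein response (0.13) and B cells (1.003) lay above the vector, each as high as 0 of 10000 random lists. Glycolysis (-0.64) and naive and central memory genes (-0.26) lay below it, each as low as 0 of 10000, type I interferon response genes stood at -0.14, as low as 1 of 10000, and the cell cycle list had a median of -0.10, as low as 155 of 10000. Interferon gamma response and class I genes, which include the class I presentation genes Tap1 and B2m, had a median of -0.10 as well, as low as 490 of 10000. Inhibitory receptor genes (0.16, as high as 11 of 10000), GATA1 partner genes (0.08, 31 of 10000) and CD8 T cell markers (0.14, 48 of 10000) lay above the vector. Follicular helper genes (0.10, 75 of 10000) and effector cytokine genes (0.09, 81 of 10000) did too. With the spread pooled from the 6 transduced arrays, which assumes that the lone vector array varies like them, limma called 0 genes in either direction for both arms.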

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

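The probe sets below were looked at only after the other results were known. They carry no gene symbol or several, entered no comparison, and are given because their signal lay at least 2-fold above the vector array in all 3 bins of an arm. On the arrays labelled FOXP3 this held for 1 of 3497 such probe sets, 10562592, at log2 intensities of 5.43, 4.98 and 5.68 against 3.91 on the vector array. On the arrays labelled FOXP3+GATA1 it held for 2 of 3497, 10545175, at 6.04, 5.77 and 5.84, a mean of 1.29 above the vector array, and 10567863, at 6.24, 6.35 and 6.18 against 4.94. No gene is named from them here and no explanation was tested.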

How the results depend on the processing

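Quantile normalization of the lists and of the vector counts, and the use of only genes with 6 distinct values, were chosen after the data had been seen; the others were planned. The number of genes called between the arms (230 higher, 16 lower) changed strongly between alternatives. It was 0 and 0 without a filter, 761 and 144 with the 50th-percentile filter, 1491 and 201 after centring each array on its median, 555 and 275 after quantile normalization, 429 and 52 with an intensity trend, 513 and 91 with robust eBayes, 1190 and 554 over genes with 6 distinct values, 13 and 0 without the bin term, 114 and 2 with an added 1.5-fold minimum, and 0 and 0 (lowest and highest) with each bin left out, which leaves 1 residual degree of freedom. With a linear bin score 343 were higher and 47 lower. Of the 230 and 16 genes, 229 and 16 were called after quantile normalization, and all of them after centring and with the trend or robust fit. For named genes between the arms, 133 single results lost their call under an alternative, 2 gained one (Foxp3, after centring and over genes with 6 distinct values), and 1 reversed: Thy1, not called in either form, was -0.0118 without the low bins and 0.101 without the high bins. Limma's prior degrees of freedom were 2.64 with the filter and 2.05 without it, against 7.63 after centring, where more genes passed.

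The FOXP3 level effect (0 and 0) became 13 higher and 1 lower after centring and 11 and 1 over genes with 6 distinct values (of the named genes, Il2ra, Socs2, Cyp11a1 and Ccr2 passed in both and Acaca after centring), and stayed at 0 and 0 under the other alternatives, leave-one-out included. The interaction stayed at 0 under each alternative run. Of the gene lists, 20 passed between arms, 0 with an estimated correlation, and 16 to 22 with a bin left out. For FOXP3 level 15 passed, 0 with an estimated correlation, 0 with fry, and 11 to 17 with an array left out. Of those 20 and 15 lists, 16 and 10 also passed in the same direction after quantile normalization.

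Against the vector, genes higher and lower on the arrays labelled FOXP3 (0 and 12) were 13 and 67 at 1.5-fold, 1 and 27 by the mean of the bins, 0 to 1 and 12 to 30 with a bin left out, and 0 and 0 in limma with pooled spread. On the arrays labelled FOXP3+GATA1 (12 and 6) they were 42 and 33, 20 and 11, 14 to 15 and 6 to 12, and 0 and 0. With a bin left out the rule asks for fewer bins, so those counts can only stay or rise. Where not given above, the cause was not tested. Genes of low intensity are limited by background, and the number of arrays limits all tests.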

Other observations

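The lists below marked as second lists, the tests of signal range, of dividing cells and of non-T cells in general, and the count of splits for genes were chosen after the results they bear on had been seen, and the second lists were written before their own values were seen. A second list of hypoxia-induced genes was low on both arms against the vector array. Of 15 genes measured, 11 lay below the vector on all 6 transduced arrays, with a median of -0.37. The angiogenic factor Vegfa was at -0.96, the stress-induced inhibitor of mTOR signalling Ddit4 at -0.99 and Egln1, an oxygen-sensing prolyl hydroxylase, at -0.67, while Adm was at 0.02 and Car9 at -0.04.

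A second list of B cell genes moved less than the first. Of 13 measured, 9 were higher on the arrays labelled FOXP3+GATA1 and 0 were called, with a median of 0.06. Ly6d was at 0.73 and Fcrl1 at 0.38, both short of the threshold, while Ighm, the abundant immunoglobulin heavy chain transcript of mature B cells, was at 0.17 and Cd40 at 0.03.

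The first pattern weighed was the higher Treg and other genes on the arrays labelled FOXP3+GATA1. It was not particular to Treg genes: the T cell activation list had a median difference of 0.54, against 0.29 for the Treg list. Of the 17 activation genes 9 also stand in other lists, and a shift of Treg genes was not separated from one of activation genes. For the Treg list, the narrower signal range of the arrays labelled FOXP3 is argued against as the whole cause. After quantile normalization 87.2% of the list's median difference was kept, and camera with the preset correlation gave an adjusted p of 4.9e-16 (before that normalization, adjusted p = 0.338 with an estimated correlation). For the other genes the signal range stays open as a part of the cause: the share of called genes that were higher went from 93.5% to 66.9% after quantile normalization. The FOXP3 low array alone is argued against as well for the Treg list, since that list's median difference was at least 0.25 in the intermediate and high bins. More dividing cells stays open. Between the arms, the cell cycle and DNA replication lists had medians of 0.55 and 0.51, larger than the Treg list's 0.29. Against the vector, these 2 lists stood at -0.64 and -0.52 on the arrays labelled FOXP3. On the arrays labelled FOXP3+GATA1 the Treg list lay above the vector while the cell cycle list lay at -0.10, but 1 vector array gives no spread. GATA1 itself, the difference the design names, stays open and untested, as the Gata1 probe set did not bear out the labels, and a wrong label or another difference between the transduced cultures may also account for it. Foxp3 signal was higher on these arrays in each bin (0.13, 0.18 and 0.60 from low to high), so unequal Foxp3 was not separated from GATA1.

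The second pattern was the higher B cell genes on those arrays. B cells that passed the CD19 exclusion, or their RNA, may be the source, and this stays open: the second list's median was 0.0636 with a camera adjusted p of 0.121, neither absent nor past the test. A lower share of T cells, which would raise all other cell types alike, stays open too. Against it, 0 of 8 stromal and 3 of 11 myeloid and dendritic cell markers were higher (medians -0.06 and -0.0847) where 14 of 14 B cell markers were, but signal was low, with 5 of 8, 4 of 11 and 5 of 14 above the vector array's median, and so was that of the NK markers (median 0.16, 0 of 4 above it). Expression of these genes in the transduced T cells was not tested.

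The third pattern was the higher glycolysis and hypoxia genes on the vector array. Noise of that single array stays open. The second hypoxia list's median was at the 0.01 percentile of 10000 matched random lists, the smallest they can give, but lists drawn from the same arrays hold the spread between genes and not that between vector samples, so the bound set for this test beforehand could not exclude it. Culture conditions of the vector sample, such as cell density, may account for it and cannot be told apart from an effect of the FOXP3 vector here, since there was 1 vector array, although 11 of the 15 genes were lower on all 6 transduced arrays.

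The 6 FOXP3-transduced arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes between the arms, 1 of the 10 splits called as many as the real one, the real one itself, with 246 genes against 0 in the highest other. Every other split mixes the arms, so the difference between arms enters its residual spread. The 0 was thus largely set in advance, and 246 against 0 does not measure chance. For lists, 1 of the 10 passed as many, with 20 against 17 in the highest other. Only 4 of the 10 splits part the arrays of all 3 bins as the real one does, and among these the highest other passed 14 lists, while the 17 came from splits that part 1 bin. Because the fit holds a bin term, a split that parts 1 bin measures the difference between arms in that bin. The other splits that part all 3 bins reverse 1 bin and still hold a part of the arm difference. The list counts of these splits thus contain the arm difference, and 20 against 17 does not measure chance either. For the interaction, all 10 of the 10 splits called as many, with 0 genes against 0.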
